A study of Mus musculus with 16 samples.

How the data were processed

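Total RNA was extracted with Trizol from cervical spinal cord (segments C3 to C5) of 16 mice, labelled with biotin through the Ambion WT Expression kit, and hybridised 1 sample per array to Affymetrix mouse gene arrays (Mouse Gene 2.0 ST). The groups, taken from the sample titles, are Gaa+/+ and Gaa-/- mice at 6 and at 16 months, 4 arrays each, and each array is taken as 1 animal.

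Per the submitters' processing notes, values were made with RMA in the affy package under R 2.15.1. The deposited table holds log2 expression, 25206 probe sets by 16 arrays with 0 missing values. Array medians (5.387 to 5.447) and spreads were nearly equal, as after a joint normalization. Probe set names are gene numbers, 1 per gene, so the probes had been regrouped by gene; the version of that regrouping, the genome build and any filter are not given in the sources used here. All 23185 probe sets that carry exactly 1 gene symbol matched by gene number to a reference gene table (GRCm38.p6), which served for names and for neighbours of Gaa. The other 2021 probe sets had no symbol and entered no comparison.

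The deposited log2 values were used as they are, with no filter on dim genes. A model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a trend or robust prior; 12 residual and 3.32 prior degrees of freedom). It gave 6 comparisons: genotype at 6 months, at 16 months and averaged over both, the difference of the genotype effect between ages, and age within each genotype. Tests were limma's moderated test, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 with no fold minimum. Replicate numbers were not used as a block. Errors given with fold changes are the SE of the model, and those given with levels are the SD over 4 arrays.

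A set of 36 gene lists, written from textbook knowledge before the data were examined, was tested with camera, with a preset correlation of 0.01 and adjustment over the 36 lists, beside camera with an estimated correlation and fry. The lists cover the lysosome, autophagy, glycogen and energy metabolism, microglia, complement, cytokines, interferon, antigen presentation, astrocytes, neurons and their channels, oligodendrocytes, vessels, ependyma, tissue around the cord (meninges, nerve root, ganglion, muscle, blood, lymphocytes), cell death, stress, the cell cycle, the clock and sex. Aldoc, Cdkn1a and Nfkbia each stand in more than 1 list. Some members of the lists are not reported here, and Gaa is in no list. For scores, each gene was centred on its mean over the 16 arrays and averaged over the list's members; scores were compared by exact permutation tests.

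The rule for named genes was fixed at the same point. It takes Gaa and, among called genes whose arrays do not overlap between the groups compared and whose brighter group reaches the median brightness, the 12 largest changes in each direction for genotype at each age and the 6 largest for the other comparisons. Predicted genes, clones, small RNAs and olfactory or vomeronasal receptors were left out, the interaction had no overlap condition, and up to 4 members with the smallest p were named within a list. Xist, the Y-linked genes, and Cxcl13 and Gpnmb for the interaction are named as members of lists.

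Alternatives fixed at that point were filters on dim genes at the 25th percentile and at the median, all probe sets, quantile normalization again, median centring and a trend and robust prior. Others were array weights, fitting only the groups compared, a replicate block, Xist as a covariate, a fold minimum of 1.2, a threshold of 0.01 and leaving out each array. Chosen after seeing the data were the meningeal score as a covariate, leaving out the pair of arrays with the highest muscle score (replicate 3 of Gaa+/+ and replicate 4 of Gaa-/- mice at 16 months), and high-Xist arrays alone. In that last fit the low-Xist arrays were kept as groups of their own for the spread. No scan dates are given in the sources used here, so batches could not be checked, and sex is not in the labels.

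The procedure was tested on simulated data with the same design, where 67, 67 and 66 of 23185 genes were changed by 0.3, 0.6 and 1.2. It called 20.9, 86.6 and 97.0 percent of these genes for genotype at 6 months, with 6 false among 142 calls, and 31.3, 79.1 and 100 percent at 16 months, with 9 false among 149. Camera recovered a simulated shift of 0.2 in the microglia list (adjusted p = 9.4e-14) and called 0 other lists. Simulated genes were independent of one another. The 0 therefore does not show how often camera falsely calls lists whose genes move together.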

Results

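Gene expression was measured on Affymetrix mouse gene arrays in the cervical spinal cord (segments C3 to C5) of Gaa-/- mice and of Gaa+/+ mice of the background strain, 129SVE. Gaa encodes acid alpha-glucosidase, the lysosomal enzyme that breaks down glycogen, and mice without it model Pompe disease. The 16 arrays form 4 groups of 4, with both genotypes at 6 and at 16 months by the sample titles. The husbandry text gives wider ranges, 6 to 8 and 12 to 16 months. The stated question is whether loss of the enzyme switches on signalling pathways tied to neuropathology. Array medians lay between 5.387 and 5.447 on the log2 scale, and the number of arrays limits the precision of every value. Xist, which female cells transcribe from the inactive X chromosome, was high (9.77 to 10.19) in 12 arrays and low (3.98 to 4.20) in 4, and the Y-linked genes Kdm5d, Eif2s3y and Uty were high in those 4. The low-Xist arrays were 2 of the 4 in each genotype at 6 months and 0 at 16 months, so genotypes were balanced for this pattern within each age and the ages were not. Each fold change below is given on the log2 scale with its standard error (SE) from the fit over all arrays.

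Gaa itself (gene number 14387) separated the genotypes in every array. It read 9.59 ± 0.07 (SD, n = 4) in Gaa+/+ and 6.28 ± 0.15 in Gaa-/- mice at 6 months, and 9.51 ± 0.06 and 6.33 ± 0.10 at 16 months. The difference was -3.31 ± 0.07 (SE; adjusted p = 2.55e-13) at 6 months and -3.18 ± 0.07 (adjusted p = 4.7e-13) at 16 months, a signal 9.92 and 9.06 times lower. The highest Gaa-/- array read 6.47 and the lowest Gaa+/+ array 9.46.

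**Figure D1:**
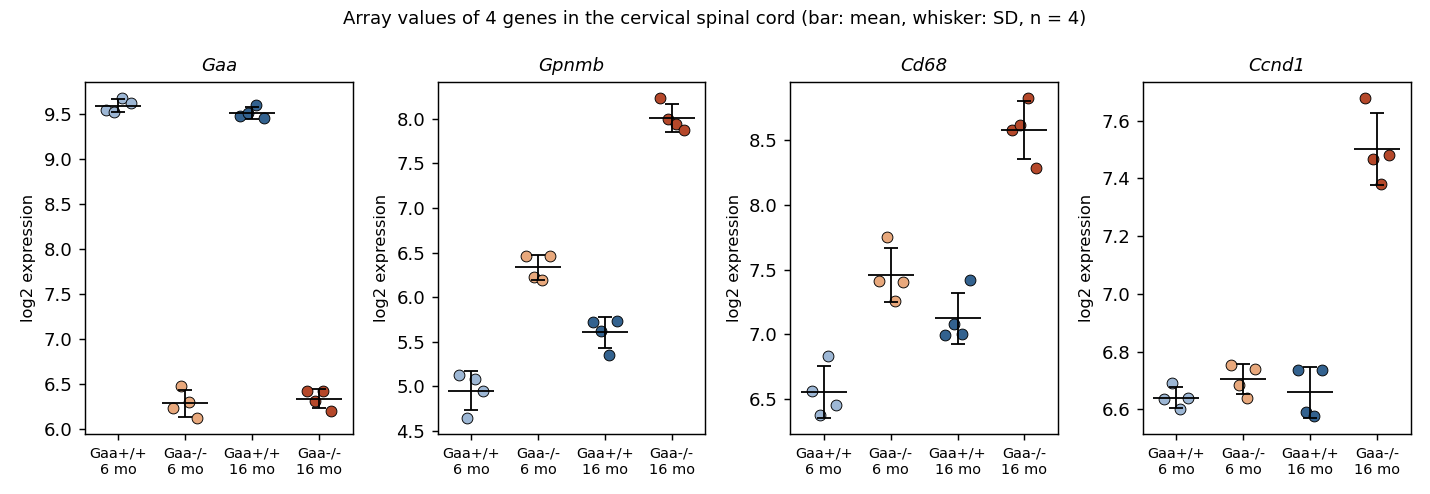
Log2 expression of Gaa, Gpnmb, Cd68 and Ccnd1 in each of the 16 arrays, by genotype and age in months; dots are arrays, bars the mean of 4 arrays and whiskers the SD. Gaa was lower in Gaa-/- mice at both ages, Gpnmb and Cd68 were higher at both, and Ccnd1 was higher in Gaa-/- mice at 16 months only, with a tested difference between ages of 0.78.

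At 6 months, the Gaa-/- spinal cord carried more transcript of genes that mark microglia and other macrophages. Gpnmb, a transmembrane glycoprotein of phagocytes, was 2.61-fold higher (1.38 ± 0.12, SE, n = 4 arrays per group; adjusted p = 2.83e-05). Mpeg1, the macrophage perforin-like protein, was 1.98-fold higher (0.99 ± 0.08; adjusted p = 2.83e-05). The chains of complement C1q, the starter of the classical complement pathway, rose together, C1qc by 0.97 ± 0.09 (adjusted p = 0.000141), C1qb by 0.83 ± 0.12 (adjusted p = 0.00688) and C1qa by 0.71 ± 0.08 (adjusted p = 0.000473). Of 23185 genes tested, 21 were higher and 2 lower in Gaa-/- mice, and 1225 had an unadjusted p under 0.05. With no effect at all, a share of about 0.05 of the genes tested would have such a p. The unadjusted counts here and below therefore include many genes that chance alone gives.

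The other named genes that rose at 6 months were Cd68, Ctse, C3ar1, Adgre1, Hpgds, Ctss and Lgals3, with changes from 0.53 (Lgals3) to 0.90 (Cd68) and adjusted p from 0.000195 (Ctss) to 0.0156 (Ctse). Cd68 is a lysosomal membrane protein of macrophages, Ctse and Ctss are cathepsins, C3ar1 is the receptor for complement fragment C3a, Adgre1 encodes the macrophage surface protein F4/80, and Lgals3 encodes galectin-3. Besides Gaa, the lower gene was Pipox, a peroxisomal oxidase (-0.42 ± 0.07; adjusted p = 0.0264).

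Gene lists fixed beforehand were tested with camera, which compares a list with all other genes, and 13 of 36 lists passed. Of 20 microglia markers, 3 rose past the threshold over all genes (C1qa, C1qb and C1qc) and 16 when adjusted over the list alone, with a median change of 0.34 (camera adjusted p = 4.79e-31). The disease-associated microglia list, genes that microglia raise around damaged tissue, had 2 of 21 members higher (Gpnmb and Lgals3) and 10 adjusted over the list alone, with a median of 0.25 (adjusted p = 1.13e-15). Lysosomal hydrolases and their activators shifted up by a median of 0.14 (adjusted p = 2.09e-17), with 3 of 33 members higher over all genes and 11 adjusted over the list alone. Those 3 were Ctss (0.64 ± 0.06), Ctsd (0.43 ± 0.05; adjusted p = 0.00158) and Hexa (0.37 ± 0.06; adjusted p = 0.028). Lysosomal membrane and proton pump genes shifted up by 0.07 (adjusted p = 5.76e-11), with Cd68 higher over all genes and 5 of 27 adjusted over the list alone. These 4 lists also passed with an estimated correlation, at adjusted p = 0.00337, 0.0117, 0.013 and 0.00173 in the order given. A further test, fry, which asks whether a list's genes move one way without comparing them with other genes, called the same 4.

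The other 9 lists called at 6 months lost the call with an estimated correlation. Reactive astrocyte genes had a median of 0.18 (adjusted p = 2.8e-08; adjusted p = 0.168 with an estimated correlation), with 0 of 27 members higher over all genes and 8 adjusted over the list alone. Complement genes had a median of 0.07 (adjusted p = 0.00103; adjusted p = 0.168 with an estimated correlation), with C3ar1 higher over all genes and 3 of 16 adjusted over the list alone. The C1q chains stand in the microglia list and not in this one. Astrocyte markers had a median of 0.08 (adjusted p = 0.000239; adjusted p = 0.231 with an estimated correlation), with Aqp4 at 0.36 ± 0.07 (adjusted p = 0.0587) and 1 member higher adjusted over the list alone. Medians were 0.05 for cytokines, 0.08 for interferon response genes and 0.05 for glycolysis genes, with adjusted p = 0.378, 0.535 and 0.496 with an estimated correlation. Oligodendrocyte and myelin markers (-0.08), endothelial and mural cell markers (-0.10) and oxidative phosphorylation genes (-0.04) were shifted down, with adjusted p = 0.535, 0.587 and 0.535 with an estimated correlation. The reactive astrocyte median was 0.115 without Gaa-/- replicate 1, and the complement median 0.131 without Gaa+/+ replicate 3 and 0.038 without Gaa+/+ replicate 1, with the calls kept. The last 6 lists had 0 members past the threshold, over all genes or adjusted over the list alone. Single arrays ended the call of 5 of them. The endothelial median was -0.004 (adjusted p = 0.474) without Gaa+/+ replicate 3. The oligodendrocyte list kept the call, with a median of -0.055 without Gaa-/- replicate 2. Oxidative phosphorylation lost the call without Gaa+/+ replicate 1 or 4 or Gaa-/- replicate 2 (adjusted p up to 0.163), and glycolysis without Gaa+/+ replicate 3 or 4 or Gaa-/- replicate 1, 2 or 3 (up to 0.16). Cytokines and interferon response genes lost it without replicate 1, 2 or 4 of either genotype (up to 0.222 and 0.264).

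The count at 6 months moved with single arrays: it was 11, 13, 15 and 43 without Gaa+/+ replicate 4, 1, 2 and 3, and 15 without Gaa-/- replicate 1 or 4. It was 6 when the 6-month groups were fitted alone. Leaving out 1 array at a time ended the call of 4 of the 14 named genes, Cd68, Ctse and Hpgds (adjusted p = 0.065, 0.0651 and 0.065 without Gaa+/+ replicate 4) and Pipox (0.122 without Gaa-/- replicate 1).

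At 16 months, markers of microglia and other macrophages were again among the genes higher in Gaa-/- mice; whether effects differed between the ages is tested further on. Gpnmb was 5.29-fold higher in Gaa-/- mice (2.40 ± 0.12, SE, n = 4 arrays per group; adjusted p = 1.35e-08). Lilrb4a, an inhibitory receptor of myeloid cells, was 4.16-fold higher (2.06 ± 0.28; adjusted p = 0.00062), and Cxcl13, a chemokine that attracts B cells, 3.40-fold (1.77 ± 0.21; adjusted p = 0.000169). Mpeg1 was 2.81-fold higher (1.49 ± 0.08; adjusted p = 7.59e-08) and Cd68 2.74-fold (1.46 ± 0.14; adjusted p = 2.12e-05). In all, 399 genes were higher and 55 lower, 29 of the 454 by more than 2-fold, and 3229 genes had an unadjusted p under 0.05. Among the called genes, 110 of the higher and 19 of the lower ones lay below the median log2 value over all probe sets and arrays (5.413).

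**Figure D2:**
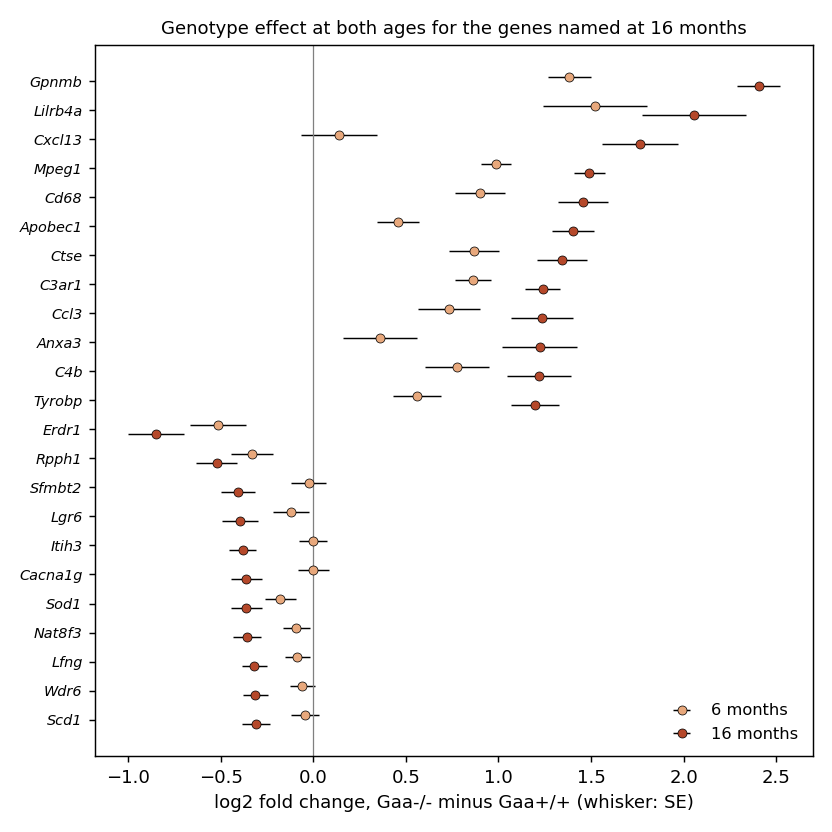
Log2 fold change between genotypes (Gaa-/- minus Gaa+/+) at 6 and 16 months for the genes named at 16 months other than Gaa; dots are estimates from 4 arrays per group and whiskers the SE. Gpnmb has the largest estimate at 16 months (2.40), and Cxcl13 lies at 0.14 at 6 months and 1.77 at 16 months.

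The remaining named genes that rose at 16 months were Apobec1, Ctse, C3ar1, Ccl3, Anxa3, C4b and Tyrobp. Apobec1 rose by 1.40 ± 0.11 (adjusted p = 5.87e-06) and Tyrobp 2.29-fold (adjusted p = 8.08e-05), and the other 5 lay between. Apobec1 edits messenger RNA, Ccl3 is a chemokine, Anxa3 is an annexin, C4b is a classical complement component and Tyrobp is the signalling adapter of Trem2. The named genes that fell did so by less: Erdr1 by -0.85 ± 0.15 (adjusted p = 0.00561), Rpph1, the RNA of ribonuclease P, by -0.52 ± 0.11 (adjusted p = 0.0214), and Sfmbt2 by -0.41 ± 0.09 (adjusted p = 0.0336). Lgr6, Itih3, Cacna1g, Sod1, Nat8f3, Lfng, Wdr6 and Scd1 fell by between -0.40 (Lgr6) and -0.31 (Scd1), with adjusted p from 0.0105 (Itih3) to 0.048 (Lgr6). Cacna1g encodes a T-type calcium channel, Sod1 the copper and zinc superoxide dismutase, and Scd1 a fatty acid desaturase.

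At 16 months 16 of 36 lists passed, and microglial and lysosomal lists had the smallest adjusted p with an estimated correlation. Of 20 microglia markers, 16 rose over all genes and 18 adjusted over the list alone, where 1 further member was lower. The median was 0.63 (adjusted p = 9.94e-30), with Trem2 at 0.96 ± 0.09 (adjusted p = 3.72e-05) and Laptm5 at 0.78 ± 0.08 (adjusted p = 3.26e-05). Of 21 disease-associated microglia genes, 12 rose over all genes and 17 adjusted over the list alone, with a median of 0.59 (adjusted p = 6.41e-25) and Cst7, a cystatin, at 0.99 ± 0.11 (adjusted p = 7.97e-05). Of 33 lysosomal hydrolases and activators, 15 rose over all genes and 22 adjusted over the list alone, with a median of 0.26 (adjusted p = 2.66e-25). Ctsd, Gusb and Hexa, a protease and a pair of glycan-cleaving enzymes, rose by 0.67 ± 0.05 (adjusted p = 4.9e-06), 0.66 ± 0.06 (adjusted p = 1.41e-05) and 0.66 ± 0.06 (adjusted p = 2.56e-05). Of 27 lysosomal membrane and proton pump genes, 6 rose over all genes and 13 adjusted over the list alone, with a median of 0.13 (adjusted p = 1.21e-13), including Npc2, a cholesterol carrier of the lysosome, at 0.43 ± 0.05 (adjusted p = 0.000152). With an estimated correlation these 4 lists had adjusted p = 0.00271, 0.00247, 0.00292 and 0.000601.

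Inflammatory and astrocytic lists also shifted up at 16 months. Of 34 cytokines, chemokines and their receptors, 7 rose over all genes and 14 adjusted over the list alone, with a median of 0.21 (adjusted p = 3.38e-09; adjusted p = 0.00328 with an estimated correlation). Among them were Cxcr4 at 0.53 ± 0.10 (adjusted p = 0.00596) and Tlr2 at 0.56 ± 0.11 (adjusted p = 0.0135). Of 27 reactive astrocyte genes, 9 rose over all genes and 14 adjusted over the list alone, with a median of 0.37 (adjusted p = 1.28e-14; adjusted p = 0.0285 with an estimated correlation). They included the protease inhibitor Serpina3n at 0.59 ± 0.05 (adjusted p = 5.87e-06) and the oncostatin M receptor Osmr at 0.93 ± 0.13 (adjusted p = 0.00101). Antigen presentation genes had a median of 0.21 (adjusted p = 2.5e-06; adjusted p = 0.0464 with an estimated correlation), with 2 of 21 higher over all genes, H2-D1 at 0.70 ± 0.07 and H2-DMb1 at 0.43 ± 0.10, and 7 adjusted over the list alone. Oligodendrocyte precursor markers had a median of 0.11 (adjusted p = 0.00106; adjusted p = 0.0375 with an estimated correlation), with 0 of 14 higher over all genes and 1 adjusted over the list alone.

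A further 4 lists shifted up at 16 months and lost the call with an estimated correlation. Complement genes had a median of 0.11 (adjusted p = 0.00124; adjusted p = 0.101 with an estimated correlation), with 4 of 16 higher over all genes and 4 adjusted over the list alone: C4b, C3ar1, Masp1 and Itgb2. Interferon response genes had a median of 0.18 (adjusted p = 1.7e-06; adjusted p = 0.0645 with an estimated correlation), with 1 of 28 higher over all genes, Irf9 at 0.41 ± 0.08, and 8 adjusted over the list alone. Astrocyte markers had a median of 0.12 (adjusted p = 0.000109; adjusted p = 0.111 with an estimated correlation). Aqp4 at 0.50 ± 0.07, Aldh1l1 at 0.42 ± 0.06 and Mlc1 at 0.26 ± 0.05 were higher over all genes, and 8 of 17 adjusted over the list alone. Glycolysis genes had a median of 0.09 (adjusted p = 0.000127; adjusted p = 0.0645 with an estimated correlation), with Pfkl higher over all genes (0.22 ± 0.05; adjusted p = 0.0394) and 6 of 18 adjusted over the list alone.

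A group of 3 neuronal lists (channels, fast transmission, and neuron and synapse markers) and the ependymal list were shifted down at 16 months, by small amounts, and each lost the call with an estimated correlation. Motor neuron markers did not pass and had a positive median (0.08). Voltage-gated and calcium channels had a negative change in 26 of 26 members, with a median of -0.11 (adjusted p = 1.1e-07; adjusted p = 0.0645 with an estimated correlation). Cacna1g was the member lower over all genes, and 2 were lower adjusted over the list alone. Genes of GABA, glycine and glutamate transmission had a median of -0.15 (adjusted p = 2.64e-06; adjusted p = 0.0858 with an estimated correlation). Gria2, an AMPA receptor subunit, was lower over all genes (-0.26 ± 0.06; adjusted p = 0.0388), and 2 of 21 adjusted over the list alone. Neuron and synapse markers had a median of -0.07 (adjusted p = 0.000989; adjusted p = 0.138 with an estimated correlation), with 0 of 20 members past either threshold. Ependymal and cilia genes had a median of -0.16 (adjusted p = 0.00763; adjusted p = 0.295 with an estimated correlation), again with 0 of 18 members past either threshold, and lost the call without Gaa+/+ replicate 1 at 16 months (-0.10; adjusted p = 0.0505).

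**Figure D3:**
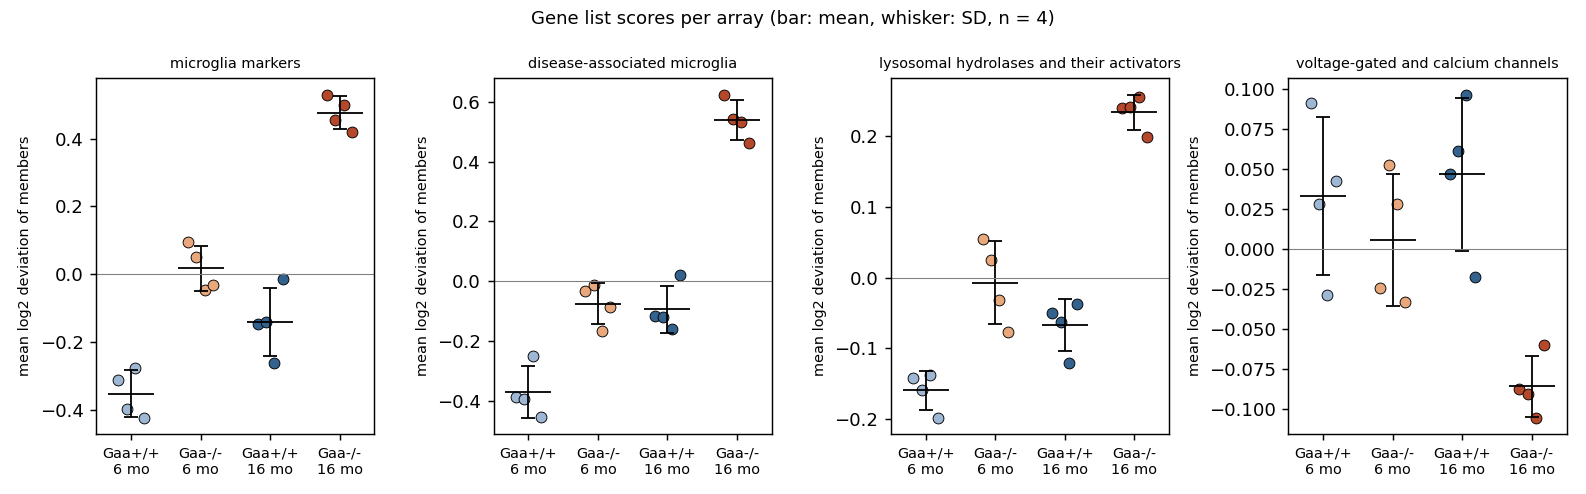
Score of 4 gene lists in each array (mean over members of the log2 value minus its mean over the 16 arrays), by genotype and age in months; dots are arrays, bars the mean of 4 arrays and whiskers the SD. The microglia score averaged -0.35, 0.02, -0.14 and 0.48 in the order drawn, and the channel score was lowest in Gaa-/- mice at 16 months (-0.09).

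The other 20 lists did not pass camera at 16 months. Of them fry called glycogen metabolism and apoptosis, both up (fry adjusted p = 0.013 and 0.0205), and it called 17 of 36 lists in all, 15 of them called by camera too. The median changes were 0.03 for autophagy, 0.07 for glycogen metabolism, 0.02 for oxidative phosphorylation, 0.08 for motor neuron markers, -0.08 for oligodendrocyte and myelin markers and -0.01 for endothelial and mural cell markers. The mean of the autophagy list was -0.001 and that of the endothelial list 0.04, of the opposite sign to their medians, and each test took the sign of the mean. Medians were 0.17 for meningeal and fibroblast markers, -0.02 for Schwann cell and nerve root markers, -0.10 for dorsal root ganglion neuron markers, -0.26 for skeletal muscle markers, -0.26 for blood cell markers and -0.07 for lymphocyte markers. They were 0.01 for apoptosis, 0.04 for endoplasmic reticulum stress, 0.01 for cholesterol biosynthesis, 0.09 for the cell cycle, -0.07 for immediate early and heat shock genes, -0.02 for the circadian clock, -0.10 for the glucocorticoid response and -0.04 for sex-linked genes. Single members past the threshold over all genes were Rb1cc1 in the autophagy list (-0.30 ± 0.05; adjusted p = 0.00668) and Gyg, the glycogen primer glycogenin (0.27 ± 0.06; adjusted p = 0.0166). Tnfrsf10b, a death receptor, also rose (0.56 ± 0.11; adjusted p = 0.0105), as did the metallothionein Mt1 (0.22 ± 0.05; adjusted p = 0.0255). Adjusted over the list alone, members also passed in the lists of motor neuron, endothelial, lymphocyte and cell cycle genes (1 each), apoptosis (2), the glucocorticoid response (2 higher and 1 lower) and the circadian clock (1 higher and 3 lower).

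At 16 months the count was 301 without Gaa+/+ replicate 2 or 3 and 294 without Gaa-/- replicate 1. Leaving out 1 array at a time ended the call of 9 of the 24 named genes, all of them lower in Gaa-/- mice: Cacna1g, Lfng, Lgr6, Nat8f3, Rpph1, Scd1, Sfmbt2, Sod1 and Wdr6, at adjusted p up to 0.162 (Lgr6, without Gaa+/+ replicate 3).

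Averaged over both ages, the genotype difference involved 379 genes that were higher and 40 that were lower in Gaa-/- mice, with 2873 genes at an unadjusted p under 0.05. Besides Gaa, the genes named for this comparison included Gpnmb (1.89 ± 0.08, SE, n = 8 arrays per genotype; adjusted p = 2.72e-09), Mpeg1 (1.24 ± 0.06; adjusted p = 7.02e-09), C3ar1, C1qa, Cybrd1 and Tlr3. C3ar1 rose by 1.05 ± 0.07 (adjusted p = 3.39e-07) and C1qa by 0.87 ± 0.05 (adjusted p = 3.39e-07). Cybrd1, an iron reductase, rose by 0.66 ± 0.06 (adjusted p = 1.22e-05) and Tlr3, a receptor for double-stranded RNA, by 0.59 ± 0.05 (adjusted p = 1.23e-05). Of the 36 lists, 16 passed, and 6 of them also passed with an estimated correlation. These were microglia markers, disease-associated microglia, hydrolases, lysosomal membrane, cytokines and reactive astrocytes, at adjusted p = 0.00116, 0.00116, 0.0017, 0.000163, 0.00532 and 0.0209. Microglia markers were higher in 17 of 20 members over all genes and in 18 adjusted over the list alone, and hydrolases in 15 and 22 of 33.

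The ages overlapped in the genes that rose. Of the 21 genes higher at 6 months, 20 were also higher at 16 months, against 0.361 if calls at the ages were independent. Both comparisons use the same estimate of spread per gene, so 0.361 is too low a benchmark. Of the 399 genes higher at 16 months, 369 had a positive change at 6 months, and of the 55 lower ones 44 had a negative change. Over all genes the log2 fold changes at the ages had a Pearson r of 0.31, and 0.29 without Gaa; this is across genes, which are not independent replicates.

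Whether the genotype effect itself differed between ages was tested as an interaction, the effect at 16 months minus that at 6 months. Low-Xist arrays were present at 6 months alone. A genotype effect that depends on sex could therefore also give such a difference, here and in the list and set tests that follow. Ccnd1, which encodes cyclin D1, was the gene that passed: the genotype effect was 0.06 at 6 months and 0.84 at 16 months, a difference of 0.78 ± 0.09 (SE, n = 4 arrays per group; adjusted p = 0.00614). The effect of Cxcl13 differed by 1.63 ± 0.29 (adjusted p = 0.154) and that of Gpnmb by 1.02 ± 0.16 (adjusted p = 0.0976), and neither passed. At an unadjusted p under 0.05 there were 1477 genes.

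By camera, 16 of 36 lists differed between ages, and 0 passed with an estimated correlation. Of these, fry called 6 in the same direction: hydrolases, lysosomal membrane, microglia markers, disease-associated microglia, cytokines and oligodendrocyte precursor markers. Their median interactions were 0.14, 0.04, 0.26, 0.31, 0.15 and 0.10, with fry adjusted p = 0.0333, 0.0158, 0.0499, 0.0158, 0.0158 and 0.0419. With an estimated correlation these lists had adjusted p = 0.141, 0.141, 0.141, 0.063, 0.063 and 0.141. The hydrolase median was 0.085 without Gaa-/- replicate 4 at 6 months, and that of lysosomal membrane genes 0.067 without Gaa-/- replicate 1 at 6 months. Over all genes 0 members passed; adjusted over the list alone, 7 microglia markers, 6 disease-associated microglia genes, 5 hydrolases and 1 cytokine gene did. The other 10 called lists included channels (median -0.08; adjusted p = 0.239 with an estimated correlation) and GABA, glycine and glutamate transmission (-0.12; adjusted p = 0.262 with an estimated correlation).

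The genes called for the average genotype effect were then tested as sets for the interaction, a test not among those fixed beforehand. The sets were picked on the same 16 arrays. Picking and testing share each gene's estimate of spread, so the p values here may be too small. The 379 higher genes had a median change of 0.24 at 6 months and 0.50 at 16 months, and the change was larger at 16 months in 355 of them (p = 0.000454 by camera with an estimated correlation, p = 0.000105 by fry). The 39 lower genes other than Gaa had medians of -0.18 and -0.28 (p = 0.000201 by camera with an estimated correlation, p = 6.7e-05 by fry). Ccnd1 kept its call without any 1 of the 16 arrays. It lost the call without the pair of arrays with the highest skeletal muscle score (0.76, adjusted p = 0.0755) and among high-Xist arrays alone (0.74, adjusted p = 0.193), both chosen after seeing the data.

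Between 6 and 16 months in Gaa+/+ mice, the background against which the knockout aged, 10 genes rose and 0 fell. In limma 1577 genes had an unadjusted p under 0.05. Mpeg1 rose by 0.70 ± 0.08 (SE, n = 4 arrays per group; adjusted p = 0.00727), Eya4 by 0.76 ± 0.09 (adjusted p = 0.00727) and C1qc by 0.59 ± 0.09 (adjusted p = 0.038). A trio of clustered protocadherins, cell adhesion molecules of neurons, rose as well: Pcdhb2 by 0.76 ± 0.12 (adjusted p = 0.0355), Pcdhb7 by 0.68 ± 0.11 (adjusted p = 0.0355) and Pcdhb13 by 0.50 ± 0.07 (adjusted p = 0.0126). Xist was 3.18 ± 1.49 higher at 16 months (adjusted p = 0.734), since low-Xist arrays were present at 6 months alone.

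Of 36 lists, 18 passed camera for age in Gaa+/+ mice, and 10 did without Gaa+/+ replicate 1 at 6 months. Xist as a covariate also lowered the count. With an estimated correlation 1 list passed, disease-associated microglia. It had a median of 0.23 (adjusted p = 1.27e-14; adjusted p = 0.0407 with an estimated correlation), with Lgals3 higher over all genes and 10 of 21 members adjusted over the list alone. Microglia markers had a median of 0.18 (adjusted p = 5.65e-13; adjusted p = 0.0927 with an estimated correlation), with C1qa and C1qc higher over all genes and 6 adjusted over the list alone. Cholesterol biosynthesis genes were shifted down by a median of -0.12 (adjusted p = 4.45e-11; adjusted p = 0.0927 with an estimated correlation), with 19 of 19 negative, 0 past the threshold over all genes and 6 adjusted over the list alone. Skeletal muscle markers had a median of 0.45 (adjusted p = 0.000525; adjusted p = 0.484 with an estimated correlation), and this median was 0.69 without Gaa+/+ replicate 2 or 4 at 16 months and -0.07 without Gaa+/+ replicate 3 at 16 months.

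The count for age in Gaa+/+ mice was 3, 6 and 3 without Gaa+/+ replicate 1, 2 and 4 at 6 months, and 0, 0 and 4 without replicate 1, 2 and 4 at 16 months. It was 6 without Gaa-/- replicate 4 at 6 months, and 5, 6 and 5 without Gaa-/- replicate 1, 2 and 3 at 16 months. With Xist as a covariate it was 4, and Pcdhb2, Pcdhb7, Pcdhb13 and C1qc lost the call, at adjusted p = 0.227, 0.227, 0.0769 and 0.227. Without replicate 2 of Gaa+/+ mice at 16 months the 6 named genes lost theirs, Mpeg1 and Eya4 at 0.0512.

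In Gaa-/- mice, 339 genes rose and 102 fell between 6 and 16 months, with 3531 at an unadjusted p under 0.05. Cxcl13 rose 4.01-fold (2.00 ± 0.21, SE, n = 4 arrays per group; adjusted p = 0.000112), Lilrb4a 3.26-fold (1.71 ± 0.28; adjusted p = 0.00531) and Gpnmb 3.20-fold (1.68 ± 0.12; adjusted p = 2.64e-06). Cybb, a subunit of the phagocyte NADPH oxidase, rose by 1.42 ± 0.14 (adjusted p = 0.000112), Anxa3 by 1.37 ± 0.20 (adjusted p = 0.00204) and C4b by 1.32 ± 0.17 (adjusted p = 0.000749). Named genes that fell were the neuropeptide genes Tac2 (-0.56 ± 0.13; adjusted p = 0.0406) and Grp (-0.45 ± 0.11; adjusted p = 0.039). The others were Pcdhgc4 (-0.51 ± 0.10; adjusted p = 0.0201), Ncmap (-0.49 ± 0.12; adjusted p = 0.05), Sfmbt2 (-0.43 ± 0.09; adjusted p = 0.0306) and Cacna1g (-0.42 ± 0.08; adjusted p = 0.0153).

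Of 36 lists, 20 passed for age in Gaa-/- mice and 8 of them also with an estimated correlation. Of 21 disease-associated microglia genes, 15 rose over all genes and 17 adjusted over the list alone, with a median of 0.49 (adjusted p = 0.00371 with an estimated correlation). Of 20 microglia markers, 13 rose over all genes and 15 adjusted over the list alone (median 0.50; adjusted p = 0.00554 with an estimated correlation), and of 33 hydrolases 11 and 18 (median 0.18; adjusted p = 0.00554 with an estimated correlation). The other lists that kept the call were lysosomal membrane and proton pump (median 0.11), cytokines (0.21), interferon response (0.25), antigen presentation (0.26) and reactive astrocytes (0.39), at adjusted p = 0.00416, 0.00416, 0.0223, 0.0302 and 0.0175 with an estimated correlation. Motor neuron markers had a median of 0.18 (adjusted p = 0.000337; adjusted p = 0.389 with an estimated correlation; 0.112 without Gaa-/- replicate 4 at 6 months), and channels one of -0.08 (adjusted p = 0.000537; adjusted p = 0.222 with an estimated correlation).

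The age changes of the genotypes overlapped: the 10 genes that rose in Gaa+/+ mice also rose in Gaa-/- mice (0.146 expected if calls were independent), and 395 of the 441 genes called in Gaa-/- mice had the same sign in Gaa+/+ mice. In each genotype 2 of 4 arrays at 6 months and 0 at 16 months were low in Xist. A sex difference would thus also make the age changes agree. The comparisons share each gene's estimate of spread as well, so 0.146 is too low a benchmark. For age in Gaa-/- mice the count was 212 with Xist as a covariate and 76 among high-Xist arrays alone, the latter chosen after seeing the data. It was 233 and 225 without Gaa-/- replicate 3 and 4 at 6 months and 225 and 213 without replicate 1 and 2 at 16 months. The call of the 6 named genes that fell, Tac2, Pcdhgc4, Ncmap, Grp, Sfmbt2 and Cacna1g, ended without at least 1 of the arrays, at adjusted p up to 0.133 (Ncmap, without replicate 1 at 16 months).

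**Figure D4:**
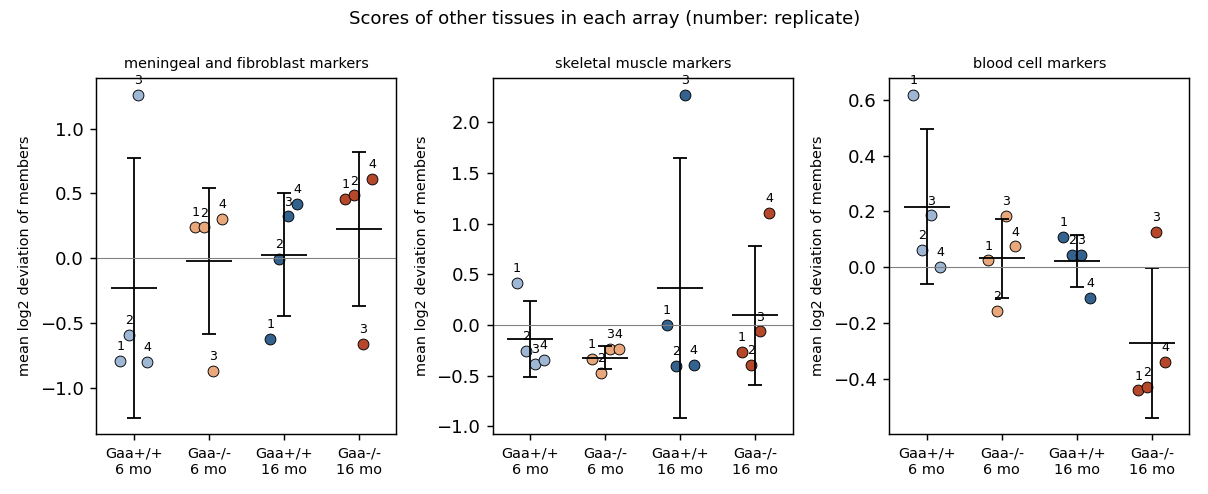
Scores of markers of meninges and fibroblasts, skeletal muscle and blood in each array (mean over members of the log2 value minus its mean over the 16 arrays), by genotype and age in months, with replicate numbers; bars are the mean of 4 arrays and whiskers the SD. The meningeal and muscle scores vary widely within groups, with a meningeal SD of 1.00 in Gaa+/+ mice at 6 months and a muscle SD of 1.28 in Gaa+/+ mice at 16 months.

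Markers of tissue around the cord varied between arrays, and the genotype differences of the meningeal and muscle scores turned on single arrays. The meningeal and fibroblast score differed between genotypes by 0.21 at 6 months (exact permutation p = 0.771, two-sided) and by 0.20 at 16 months (exact permutation p = 0.514). The difference at 6 months was 0.71 without Gaa+/+ replicate 3, 0.49 without Gaa-/- replicate 3 and 0.02 without Gaa+/+ replicate 1 or 4. At 16 months it was -0.02 without Gaa+/+ replicate 1 and 0.49 without Gaa-/- replicate 3. The skeletal muscle score differed by -0.18 (exact permutation p = 0.629) and -0.27 (exact permutation p = 0.771). Its sign turned without Gaa+/+ replicate 1 at 6 months (0.005) and without Gaa+/+ replicate 3 at 16 months (0.36). The blood cell score differed by -0.19 (exact permutation p = 0.371) and -0.29 (exact permutation p = 0.143). It was -0.05 without Gaa+/+ replicate 1 at 6 months, and negative without any 1 array at either age. The smallest p that 4 against 4 arrays allow is 0.0286.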

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

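Among the tests in this part, those of the microglial state, of blood, of meningeal tissue by a covariate and of the regrouping with covariates were chosen only after the result was seen.

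Microglial, lysosomal and cyclin D1 expression stand first here, because their genotype effect differed between the ages by a test of the difference. Low-Xist arrays stood at 6 months alone, so a genotype effect that depends on sex could also give this difference over all arrays. Ccnd1 differed by 0.78 (adjusted p = 0.00614). By fry the median of a list differed by 0.31 for disease-associated microglia, 0.26 for microglia markers, 0.14 for lysosomal hydrolases, 0.15 for cytokines, 0.10 for oligodendrocyte precursor markers and 0.042 for lysosomal membrane genes. With an estimated correlation in camera 0 of these 6 lists passed. Of 100 groupings of the arrays, 3 called as many genes for this difference as the real one, which called 1, and the highest other count was 1. A count of 1 leaves the groupings nothing to exceed, and exchanging ages adds the age effect to the spread, so they decide nothing about chance.

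The rise of microglial lists at 16 months was weighed against technical sources and against a shift in cell number alone. More meningeal tissue is argued against, because with the meningeal score as a covariate the median of the microglia list was 0.99 of its value without. Blood left in the tissue is argued against too: the blood cell score differed by -0.29 between Gaa-/- and Gaa+/+ mice (exact permutation p = 0.143, two-sided), and even the highest Gaa-/- array exceeded the lowest Gaa+/+ array by 0.23, less than the rise of 0.63. More microglia of unchanged state and a change of their state cannot be told apart. The disease-associated score rose beyond that of 10 homeostatic genes by 0.28 (exact permutation p = 0.0286, two-sided, the smallest possible), by 0.33 on brighter members and by 0.16 without Tmem119 and Sall1 (each exact permutation p = 0.0286). Those genes were picked with their values known, which favours a gap. Against the whole microglia list, fixed beforehand, the gap was 0.02 (exact permutation p = 0.457). That list also holds Trem2, Tyrobp and Laptm5, which rose themselves, so a small gap there does not speak for an unchanged state. Neither comparison decides the question.

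Other groupings of the same arrays were counted for each comparison. For genotype at 6 months 1 of 35 splits, the real one, called as many genes as the real one (23). The highest other count was 16, in the split that exchanges replicate 3 between the genotypes. For genotype at 16 months it was also 1 of 35 (real 454, highest other 0). For the average it was 2 of 100 (real 419, highest other 542), again a grouping that exchanges replicate 3 of both genotypes at 6 months. It keeps the genotypes at 16 months as they are, so part of its count comes from the real difference. A count above the real one points to a structure of the samples. The exchange puts 3 low-Xist arrays in 1 regrouped arm at 6 months and 1 in the other, and parts the mean meningeal levels to 6.01 and 7.29. With a covariate the regrouping called 189 genes (meningeal score), 396 (Xist) or 160 (both), and the real grouping 454, 460 and 450. The Gaa levels of the exchanged arrays (9.67 and 6.30) match their labels, which speaks against exchanged samples. For age in Gaa+/+ mice it was 1 of 35 (real 10, highest other 0). For age in Gaa-/- mice it was 1 of 35 (real 441, highest other 22). A share of 1 of 35 is the smallest that 35 splits allow. Exchanging arrays adds the real difference to the spread, which lowers the other counts. These splits therefore do not by themselves exclude chance.

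A single array lay far from the other 3 of its group in 16 of 316 groups tested by Dixon's ratio, and chance gives about 1 in 20, or 15.8. Meningeal and fibroblast markers held the highest ratio, in Gaa-/- mice at 6 months. Replicate 3 was high in Gaa+/+ mice at 6 months (8.04 against 5.97 to 6.19; ratio 0.897). It was low in Gaa-/- mice at 6 months (5.91 against 7.01 to 7.08; 0.943) and at 16 months (6.11 against 7.23 to 7.39; 0.876). Skeletal muscle markers were high in replicate 1 of Gaa+/+ mice at 6 months (0.841) and in replicate 3 at 16 months (7.07 against 4.40 to 4.80; 0.849). The complement score was high in replicate 3 of Gaa+/+ mice at 6 months (0.878). Oxidative phosphorylation (0.908) and cholesterol biosynthesis (0.874) were high in replicate 3 of Gaa-/- mice at 6 months, and reactive astrocyte genes were low in replicate 3 of Gaa-/- mice at 16 months (0.85). Among genes, in Gaa+/+ mice at 6 months, Ctss was low in replicate 4 (0.834), Tyrobp low in replicate 2 (0.908), Pcdhb2 low in replicate 3 (0.899) and Cybb high in replicate 3 (0.844). At 16 months, Tlr3 was low in replicate 3 of Gaa+/+ mice (0.858), and in Gaa-/- mice Tyrobp was low in replicate 4 (0.846) and Cacna1g high in replicate 1 (0.906).

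Probe sets without a gene name, left out of every comparison, carried differences as well. Tested with all others, 2 passed for genotype at 6 months, 27 for genotype at 16 months, 31 for the average and 24 for age in Gaa-/- mice.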

How the results depend on the processing

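Among the tests here, those with the meningeal score as a covariate, without the pair of arrays of highest muscle score, and with high-Xist arrays alone were chosen only after the result was seen. Gaa kept its direction and its call throughout, from -3.37 to -3.26 at 6 months and from -3.21 to -3.13 at 16 months with 1 array left out, and no called result changed to a call in the other direction. Counts of genes moved as follows, and the cause was not tested unless given. For genotype at 6 months (23) the count was 38 and 43 with dim genes left out at the 25th percentile and at the median, where fewer genes are tested, 41 with a trend and robust prior, and 6 with only the groups compared. Between the genotypes at 6 months, arrays of the same replicate number did not pair (r of -0.36 to -0.127 after removal of group means). Between the ages in Gaa-/- mice that r was 0.091 to 0.279. The count for genotype at 6 months was 11 with a replicate block, 11 at the stricter threshold of 0.01 and 12 with high-Xist arrays alone. At 16 months (454) and on average (419) it was 242 and 238 at 0.01. For the difference between ages (1) it was 4 with dim genes left out at the median, 5 with the trend and robust prior, and 3 with array weights. It was 2 with Xist as a covariate and 0 without the pair of muscle arrays, where limma's unadjusted count over the 16 arrays is 1477. For age in Gaa+/+ mice (10) it was 25, 20 and 19 with dim genes left out at the median, the trend and robust prior, and array weights. It was 0 with only the groups compared (limma's unadjusted count over the 16 arrays is 1577), 4 with Xist as a covariate, 2 at 0.01, 4 without the muscle arrays and 5 with high-Xist arrays. For age in Gaa-/- mice (441) it was 187 with only the groups compared, 212 with Xist as a covariate, 137 at 0.01 and 76 with high-Xist arrays, where fewer arrays are compared. Called lists fell from 13, 16, 16, 16, 18 and 20, in the order of the comparisons, to 4, 8, 6, 0, 1 and 8 with an estimated correlation. Fry called 4 at 6 months, 6 for the difference and 4 for age in Gaa+/+ mice, and Xist as a covariate left 8 for age in Gaa+/+ mice. With 1 array left out, counts of genes ranged from 11 to 43, 294 to 499, 331 to 470, 1 to 2, 0 to 14 and 213 to 475. Lists ranged from 9 to 15, 16 to 19, 16 to 19, 13 to 19, 10 to 19 and 18 to 23. The remaining settings, among them normalizing again, centring and a fold minimum of 1.2, left counts within 1.5 times. Averaging probe sets per gene was not run, since each gene has 1. Named genes lost the call in 31, 81, 0, 2, 54 and 67 of their tests across settings and kept it in 346, 586, 168, 26, 120 and 281. Dim genes are among the calls: 110 of the 399 genes higher at 16 months lie below the median log2 value over all probe sets and arrays.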

Other observations

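Among the tests in this part, the comparison of channels with neuron markers, the meningeal covariate, the high-Xist arrays and the tally of lower genes against ageing were chosen only after the result was seen.

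Homeostatic microglial genes, which mark resting microglia, were mostly higher in Gaa-/- mice at 16 months. Of 10, 8 had a positive change and 6 passed, with a median of 0.41. Fcrls (0.97 ± 0.15, SE, n = 4 arrays per group; adjusted p = 0.0013) and Cx3cr1 (0.43 ± 0.08; adjusted p = 0.00856) rose, as did Csf1r (0.40 ± 0.07; adjusted p = 0.00282), Siglech (0.41 ± 0.10; adjusted p = 0.0342), P2ry13 (0.40 ± 0.09; adjusted p = 0.0225) and P2ry12 (0.33 ± 0.07; adjusted p = 0.0199). Gpr34 (0.46 ± 0.13; adjusted p = 0.1), Olfml3 (0.43 ± 0.11; adjusted p = 0.0513), Tmem119 (-0.09 ± 0.07; adjusted p = 0.577) and Sall1 (-0.23 ± 0.09; adjusted p = 0.259) did not pass. These genes were chosen after their values were seen.

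Median changes of 3 neuronal lists were negative in Gaa-/- mice at 16 months, with 26 of 26 channels negative, while that of motor neuron markers was positive (0.08). Each of the 3 called lists lost its call with an estimated correlation. There the adjusted p was 0.0645 for voltage-gated and calcium channels, 0.0858 for GABA, glycine and glutamate transmission and 0.138 for neuron and synapse markers. The scores of these lists differed between genotypes by -0.133, -0.125 and -0.072 in that order. By exact permutation, two-sided and not adjusted over the lists, p was 0.0286, 0.0571 and 0.0571. More meningeal tissue is argued against as the whole cause, since the channel median with the meningeal score as a covariate was 0.92 of that without. An even dilution of neuronal RNA by other cells would lower channels and neuron markers alike. Channel minus marker scores differed between genotypes by -0.06 (exact permutation p = 0.0286, two-sided, the smallest possible), and by -0.055 without channels that muscle also expresses. Between the 13 brighter channels and the 10 dimmer neuron markers the difference was 0.006 (exact permutation p = 0.8), so dilution and lower channel expression cannot be told apart, because dim and bright probe sets may respond unequally. Lower channel expression in neurons stays open, as a hypothesis.

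Genes called for age in Gaa-/- mice were weighed against the sex pattern, since low-Xist arrays stand at 6 months alone. Among high-Xist arrays the median change of the 441 genes was 0.943 of that over all arrays, with the same sign in 441. These genes were called with the same arrays, which favours a kept sign and size. The values therefore speak only weakly against sex as the whole cause, and a part of it stays open. Fewer arrays left 76 genes called, and the count also fell with Xist as a covariate. With the meningeal score as a covariate 487 genes were called, so the count did not fall. A covariate can also lower the spread and raise a count, so this alone does not decide on meningeal tissue. Ageing itself remains a candidate explanation, and the wider age ranges in the husbandry text leave the exact ages open.

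A knockout carried on another strain background could keep flanking sequence of the donor strain, which would place changed genes near Gaa. Of the 418 genes called for the average effect other than Gaa, 0.718 percent lay within 10 Mb of it (Lgals3bp, Socs3 and Sox9), against 1.02 percent of all genes (Fisher exact p = 0.804, two-sided; gene order from GRCm38.p6). Within 5 and 20 Mb the shares were 0.478 and 1.91 percent (exact p = 0.592 and 1), so flanking sequence is argued against as a source of many calls.

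A further hypothesis is that genes raised by loss of Gaa also rise as Gaa+/+ mice age. Of the 399 genes higher at 16 months, 69.9 percent had a positive age change in Gaa+/+ mice, against 44.2 percent of all genes. The Gaa+/+ arrays at 16 months enter both comparisons with opposite sign, which lowers this share. In 100 simulations with no genotype or age effect it was 5.51 to 13.3 percent. Simulated genes were picked from noise alone and were independent. That range is therefore too low and too narrow for genes with a real genotype difference. With the Gaa+/+ arrays at 16 months divided between the comparisons in 6 ways, the share was 79.2 to 90.3 percent of 107 to 216 genes. Among high-Xist arrays it was 65.2 percent. The higher genes go with the hypothesis, which may reflect microglial genes that rise in both; their median age change was small (0.08). The lower genes do not settle a wider one. Of the 54 other than Gaa, 27.8 percent had a negative age change, against 55.8 percent of all genes. The shared arrays lower this share too, so 55.8 percent is not its value without a common change. Simulations gave 0 to 16.7 percent, with the limits named above. The divided arrays called 1 to 9 such genes, too few to tell. Negative were 4 of 9, 2 of 3, 1 of 1, 5 of 7, 2 of 2 and 5 of 6. Over all genes the changes had a Pearson r of -0.112 (simulated mean -0.502), and 0.045 to 0.197 with the arrays divided, across genes that are not independent replicates.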
